A study of Arabidopsis thaliana with 4 samples.

How the data were processed

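Poly(A)-selected RNA from whole Arabidopsis thaliana seedlings of the prt6-1hyt1-1 double mutant was sequenced in 4 libraries, which the labels call biological replicates 1 to 4. The seedlings were 7 days old, grown in continuous light on agar medium without sucrose and harvested untreated, per the labels. A directional kit was used for the libraries, and the library pool was sequenced on a NextSeq500. The title of replicate 4 spells the genotype with 2 characters exchanged, which was read as a misprint. In the deposited table the 4 columns name hup40 where the labels name hyt1. The columns were matched to the labels by the prt6-1 name and the replicate number, and neither hup40 nor hyt1 is tied to a gene in the sources used here.

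The deposited values are raw read counts per gene, and the authors made them with HISAT2 2.1.0 and featureCounts 1.6.0 on the genome build TAIR10, per the submitters' processing notes. The strand setting, the annotation release and the handling of reads that map to several places or overlap several genes are not given in the sources used here. If reads with several best positions were dropped, genes with near-identical copies are undercounted, and if strand was not used, a gene and its antisense neighbour share reads. The table has 37885 gene identifiers, 0 of which are chloroplast- or mitochondrion-encoded. The planned share of organelle transcripts therefore has no value.

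Of these identifiers, 37882 matched the TAIR10.1 annotation, which supplied gene symbols, positions and exon lengths, and 3 did not. Positions are on TAIR10.1, a build other than the one named by the submitters, and counts were never assigned by them. A gene without a symbol in that annotation is named by its identifier. Length-normalised levels (TPM) were computed from the count plus 0.5, divided by the summed length of the gene's merged exons. Depth-normalised counts (CPM) used library sizes scaled by the trimmed mean of M values (TMM). TPM is a level within a library, and lengths of merged exons overstate the transcript for genes with several isoforms.

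With a single group, no difference between groups could be tested. The variation between libraries was estimated in edgeR 4.0.16 under R 4.3.3 with an intercept-only model and the 19940 genes that its expression filter kept, as a biological coefficient of variation (BCV) per gene and its trend with expression. A chi-square test of homogeneity, with Benjamini-Hochberg adjustment at 0.05, counted the genes whose counts varied more than counting error. It was applied to genes with at least 10 expected counts per library. The 14 gene lists, with 221 genes, the 15 pairs of genes and the rule for naming genes were fixed before the data were examined, and 6 genes belong to more than 1 list. The lists cover low-oxygen response, the N-degron pathway, its substrates, photosynthesis, seed storage and late embryo, root, ethylene, touch and wounding, heat shock, circadian clock, abscisic acid and drought, flavonoid synthesis, cell division and qPCR reference genes.

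Except under the alternatives below, members that did not pass the filter did not enter the level, variation or deviation of a list. A list with many low members can therefore read too high in level. The level of a list was the median log2 TPM of the members that passed, placed among 10000 random lists of the same size drawn from the genes kept. Its variation was the median excess of the BCV over the trend, and its deviation in a library was the median difference of log2 CPM from each gene's mean over the libraries. Both were placed among 10000 random lists matched on mean expression in 20 bins, with a two-sided Monte Carlo p and Benjamini-Hochberg adjustment. Deviations are taken from a gene's own mean, so the tests of a list in different libraries are not separate results. The p-values describe the 4 libraries and treat genes as independent. Genes of a pathway are usually co-regulated, so the p-values are too small as statements about other seedlings. Pairs of genes were compared as log2 TPM ratios within each library, with an exact two-sided sign-flip test. With 4 libraries there are 16 sign patterns and 2 of them are the most extreme, so this test cannot reach 0.05.

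The named genes were all members of the N-degron and substrate lists, the 10 highest, 3 lowest and 3 most variable members of the low-oxygen list, the highest and lowest members of every other list, the 3 most variable members of lists that passed the variation test, the 10 most abundant genes, the 10 most variable genes with a mean of at least 10 CPM, and both genes of each pair. Genes named outside this rule were chosen after their values were seen and are marked so where they appear, and copies of a named gene were named with it. A result that this rule calls for is not reported here. Near-identical copies were searched with BLAST 2.17.0, at 98% identity or more over at least 90% of the transcript, and 188 genes with a count have such a copy. DESeq2 1.42.0 served as an alternative.

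The total count per library ranged from 24743656 to 26155431. Simulated data had the means and library sizes of these libraries for the 19940 genes kept, and 19856 of them passed the filter again. A 2-fold change in 1 library was called beyond counting error for 100% of 100 changed genes and a 4-fold change also for 100%. The changed genes had a mean of at least 20 counts. Those data also held spread between libraries at a common BCV, and the share of their unchanged genes that was called was not recorded. Among the 19851 genes that passed the filter in data simulated without spread beyond counting, 0% were called. All 20 lists of genes changed 2-fold and 0 of 20 lists of unchanged genes passed the Monte Carlo test. Changes under 2-fold, such as most list deviations in the results, were not simulated, so the sensitivity to them is not known. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The alternatives tried were other scaling, filters, dispersion estimates, backgrounds, summaries, numbers of bins and pseudocounts, and leaving out each replicate.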

Results

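The data describe the transcriptome of Arabidopsis seedlings that carry both the prt6-1 and the hyt1-1 mutations. PRT6 is the ubiquitin ligase of the N-degron pathway that leads group VII ethylene response factors (ERFVIIs) to degradation when oxygen is present. The design sets this double mutant beside earlier data from Col-0, prt6-1 and a prt6-1 line without ERFVIIs. Those libraries were not analysed here, so no comparison between genotypes was made. The question open to these data is which transcripts were abundant in the double mutant, and how far they differed between replicate seedling samples. The 4 libraries held 24743656, 26155431, 25804589 and 24947145 counts for replicates 1 to 4. At least 1 count was found for 23904 ± 268 genes (SD, n = 4), and at least 10 counts for 20735 ± 50.9 genes. Protein-coding genes took 99.5% ± 0.0189 of the counts.

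PRT6 (AT5G02310, chromosome 5, 473868 to 482942 on the plus strand, protein-coding, TAIR10.1) had 1659, 2016, 1858 and 1841 counts in replicates 1 to 4. Its mean was 72.6 ± 4.66 CPM and 16.6 ± 0.939 TPM (SD, n = 4). A count over all exons includes transcript on either side of an insertion or a point mutation, and no library with intact PRT6 was analysed here, so these counts do not check the label. The BCV of PRT6 was 0.0590, beside 0.0587 for the trend of genes at its expression.

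Low-oxygen response transcripts stood high in these untreated seedlings. The median of the 44 list members past the filter lay at log2 TPM 4.68 ± 0.20 (SD, n = 4), above 99.6% of random lists of the same size. Of the 45 members, 9 were in the top 10% of genes by TPM, 31 were above the median gene and 14 were not. The highest was HB1 (AT2G16060, chromosome 2, 6982531 to 6983777, minus strand), a non-symbiotic haemoglobin, at 148 ± 17.0 TPM. It was followed by AT4G27450 at 129 TPM, the lipocalin gene TIL (AT5G58070) at 112 TPM, AT3G03270 at 111 TPM, AT3G10020 at 109 TPM and SAD6 (AT1G43800) at 104 TPM. The plant cysteine oxidase gene PCO1 (AT5G15120) reached 102 ± 6.67 TPM, LBD41 (AT3G02550) 95.1 TPM, the alanine aminotransferase gene ALAAT1 (AT1G17290) 90.5 TPM and AT4G39675 81.3 TPM. Without length normalisation the list lay at percentile 91.2. A high percentile was not particular to this list. With length normalisation, reference genes lay at percentile 100, ethylene genes at 97.2 and clock genes at 95.5. Other lists lay lower, such as heat shock at 19.5 and abscisic acid and drought at 4.64. No library of another genotype was analysed here, so the level does not measure an effect of the mutations.

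Among genes of fermentation and sucrose breakdown in the same list, ADH1 and PDC2 lay above the median of the list and PDC1, SUS1 and SUS4 below it. Alcohol dehydrogenase ADH1 (AT1G77120, chromosome 1, 28975255 to 28977417, plus strand) stood at 47.5 ± 7.26 TPM. The pyruvate decarboxylase gene PDC2 (AT5G54960) was at 52.5 ± 3.43 TPM and PDC1 (AT4G33070) at 19.1 ± 1.91 TPM. The sucrose synthase genes SUS1 (AT5G20830) and SUS4 (AT3G43190) were at 16.8 ± 1.53 and 13.5 TPM, and their sequences are similar enough that the split of reads between them is uncertain. The lowest members were FHL (AT5G02200) at 0.999 TPM, the aquaporin gene NIP2;1 (AT2G34390) at 1.04 TPM and AT5G45960 at 1.36 TPM.

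**Figure D1:**
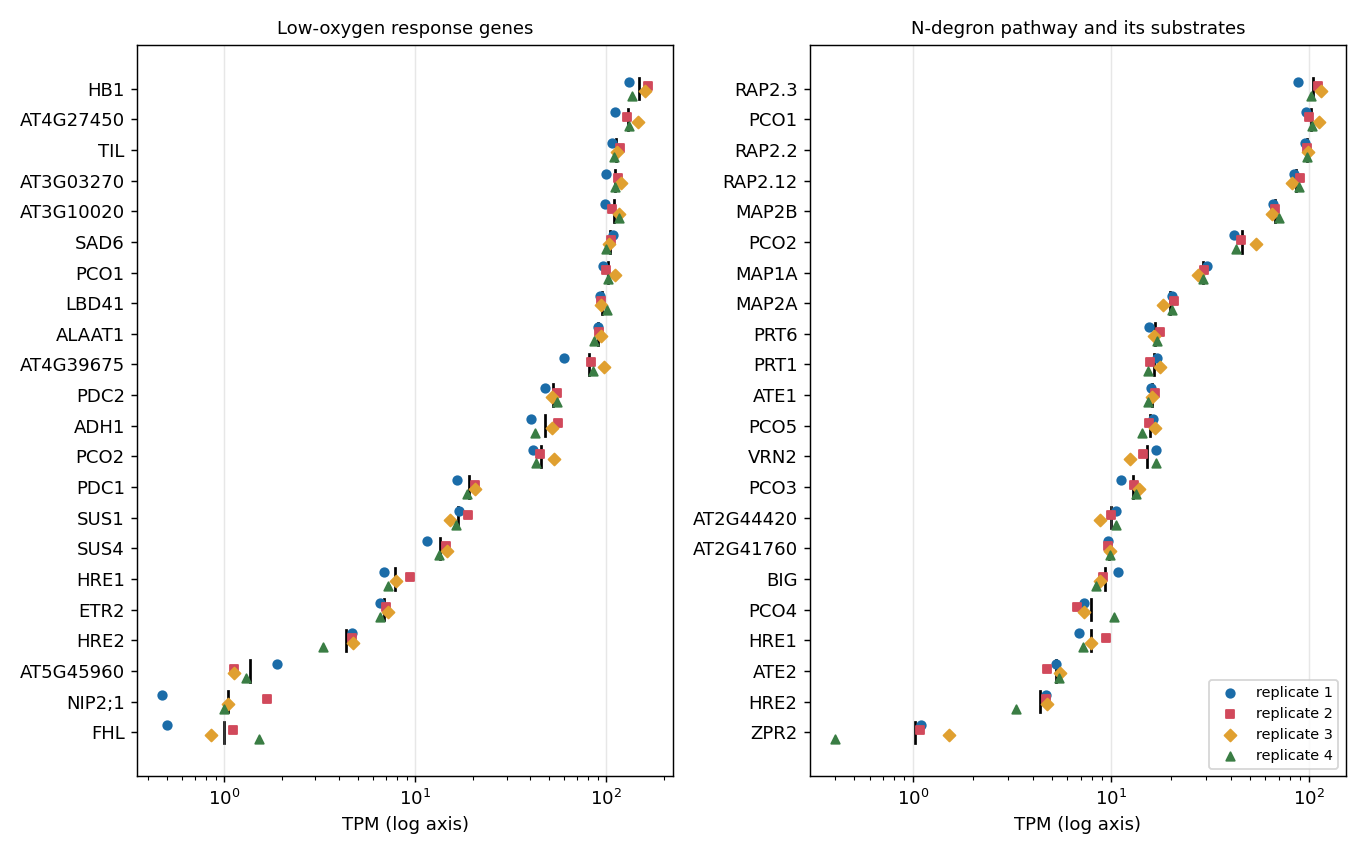
Transcript levels in TPM on a log axis for members of the low-oxygen response list (left) and of the N-degron pathway with its substrates (right). Each symbol is a library and each vertical bar the mean of the 4 libraries. HB1 leads the left panel at 148 TPM, and RAP2.3 and PCO1 lead the right panel at 104 and 102 TPM.

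The low-oxygen list also differed between the replicate samples, with the lowest values in replicate 1 and the highest in replicate 3. Replicate 1 also stood apart across all genes, at 27.4 on the first principal component, beside -12.5 to -6.14 for the others. The second component set replicate 3, at 22.5, against replicate 4, at -16.5, with the others at -6.52 and 0.57. The median deviation of the list was -0.15 on the log2 scale in replicate 1, 0.06 in replicate 2, 0.12 in replicate 3 and -0.05 in replicate 4, and all 4 passed the Monte Carlo test over 56 pairs of list and library (adjusted p 0.0016, 0.0016, 0.0016 and 0.0173). These 4 tests are not separate results, since a low value in 1 library raises a gene's deviation in the others. With the mean of the list, replicate 4 did not pass, at -0.0400 (adjusted Monte Carlo p 0.179). Of the 44 members that passed the expression filter, 27 (61.4%) were lowest in replicate 1 and 26 (59.1%) were highest in replicate 3. Of all 19940 genes, 28.5% were lowest in replicate 1 and 26.1% were highest in replicate 3. Other lists differed in this: 7 of 12 reference genes were lowest in replicate 1, and 1 of 13 touch and wounding genes. The median deviation of the reference genes in replicate 1 was -0.06 and did not pass (adjusted Monte Carlo p 0.134). A fall in replicate 1 was therefore not particular to low-oxygen genes. Counts of 42.7% of all 19940 genes varied by more than counting error, a call that comes more easily at high counts. All 29 photosynthesis genes had this call, though that list did not pass the variation test. So did 32 of the 44 low-oxygen members. By excess over the trend the most variable were NIP2;1, with 10, 39, 24 and 22 counts, FHL, with 12, 29, 22 and 38 counts, and the phloem protein gene PP2-A13 (AT3G61060), with 905, 1215, 1490 and 1312 counts. ADH1 had 1023, 1494, 1380 and 1090 counts. The excess variation of the list passed its own Monte Carlo test (adjusted p 0.0014 over 14 lists). Without replicate 1 it fell from 0.0092 to 0.0028 beyond matched lists, in BCV, and still passed (adjusted Monte Carlo p 0.0161).

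Enzymes of the N-degron pathway ranged from PCO1 to ATE2 in level, and no more variation than in matched lists was detected. All 15 listed members passed the filter, and their median log2 TPM of 3.98 ± 0.04 (SD, n = 4) lay at percentile 63.8. That percentile was 77.9 without length normalisation, 77.5 with the mean of the list and 88.7 against all genes with a count. After PCO1, the highest were the methionine aminopeptidase gene MAP2B (AT3G59990) at 67.0 ± 2.40 TPM and PCO2 (AT5G39890) at 45.7 ± 5.41 TPM. MAP1A (AT2G45240) was at 29.1 TPM, MAP2A (AT2G44180) at 19.8 TPM, the ubiquitin ligase gene PRT1 (AT3G24800) at 16.3 TPM and the arginyltransferase gene ATE1 (AT5G05700) at 15.95 TPM. PCO5 (AT3G58670) stood at 15.7 TPM, PCO3 (AT1G18490) at 12.8 TPM, AT2G44420 at 9.98 TPM, AT2G41760 at 9.74 TPM, BIG (AT3G02260) at 9.26 TPM, PCO4 (AT2G42670) at 7.90 TPM and ATE2 (AT3G11240) at 5.23 TPM. Counts varied beyond counting error for 6 of the 15 members, beside 42.7% of all genes kept, and the list did not pass the variation test (adjusted Monte Carlo p 0.644). Both PCO1 and PCO2 also belong to the low-oxygen list.

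Among the substrates of the pathway, the 3 RAP-type ERFVIIs were far more abundant than the 2 HRE genes. RAP2.3 (AT3G16770, chromosome 3, 5705541 to 5707084) stood at 104 ± 11.8 TPM, RAP2.2 (AT3G14230) at 96.9 ± 1.63 TPM and RAP2.12 (AT1G53910) at 85.7 ± 3.61 TPM. HRE1 (AT1G72360) was at 7.85 ± 1.14 TPM and HRE2 (AT2G47520) at 4.33 ± 0.701 TPM, the latter from 44 to 66 counts per library. VRN2 (AT4G16845), a subunit of Polycomb repressive complex 2, was at 15.1 ± 2.09 TPM. ZPR2 (AT3G60890) did not pass the filter, at 1.02 TPM. The list had percentile 94.3 by level and did not pass the variation test (adjusted Monte Carlo p 0.424). RAP2.3 had 1826, 2433, 2507 and 2148 counts and was lowest in replicate 1, like the low-oxygen list, which shares only HRE1 and HRE2 with this one.

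Ratios within each library placed related genes against each other. PDC1 was below PDC2 in 4 of 4 libraries, at a mean log2 ratio of -1.46 ± 0.10 (SD, n = 4, exact sign-flip test). PCO1 exceeded PCO2 by 1.17 ± 0.09 and PCO4 by 3.71 ± 0.28, and PCO2 exceeded PCO5 by 1.54 ± 0.13. ADH1 exceeded PDC1 by 1.31 ± 0.10, HRE1 exceeded HRE2 by 0.86 ± 0.26 and SUS1 exceeded SUS4 by 0.32 ± 0.22. HRE2 stood at -4.32 ± 0.29 relative to RAP2.12, and RAP2.12 at -0.18 ± 0.06 relative to RAP2.2. ATE1 exceeded ATE2 by 1.61 ± 0.14 and VRN2 exceeded ZPR2 by 4.03 ± 0.98, where ZPR2 had as few as 6 counts. MAP2A stood at -1.76 ± 0.06 relative to MAP2B, and the ethylene receptor gene ETR2 (AT3G23150) at -1.26 ± 0.13 relative to ETR1 (AT1G66340). Each of these ratios had 1 sign in all 4 libraries, which 2 of the 16 sign patterns do, so none can pass 0.05. RAP2.12 to RAP2.3 was -0.27 ± 0.18 with length normalisation and 0.28 without it, so their order is not settled. PRT6 to PRT1 was 0.02 ± 0.16, with both signs among the libraries (exact sign-flip p 0.75). Without length normalisation it was 2.102, since PRT6 is the longer gene.

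Photosynthesis transcripts were the most abundant of the lists. The 29 listed genes took 10.3% ± 0.215 of the counts, all 29 were in the top 10% of genes by TPM, and their median lay above 100% of random lists. The 10 most abundant genes of the table took 7.08% ± 0.123. They were the light-harvesting genes LHCB1.3 (AT1G29930) at 16473 ± 697 CPM, LHB1B2 (AT2G34420) at 5649 CPM and LHCB5 (AT4G10340) at 4006 CPM, the Rubisco small subunit genes RBCS1A (AT1G67090) at 14774 ± 402 CPM and RBCS3B (AT5G38410) at 4424 CPM, Rubisco activase RCA (AT2G39730) at 9038 ± 569 CPM, the oxygen-evolving complex genes PSBO1 (AT5G66570) at 3923 CPM and PSBP1 (AT1G06680) at 3361 CPM, the beta-glucosidase gene PYK10 (AT3G09260) at 5043 CPM and the thiamine synthesis gene THI1 (AT5G54770) at 4067 CPM. Members of the LHCB1 and RBCS families resemble each other, so the split of reads within each family is uncertain. PETE1 (AT1G76100), a plastocyanin gene, was the lowest of the photosynthesis list at 257 TPM. The list lay below its matched lists in replicate 4, at a deviation of -0.07 (adjusted Monte Carlo p 0.0016), and 20 of its 29 members were lowest there. The reference genes lay above 100% of random lists, from AT5G60390 at 1110.5 TPM to AT2G28390 at 23.4 TPM. Neither list passed the variation test (adjusted Monte Carlo p 0.290 and 0.644).

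Seed storage transcripts were near the bottom of the transcriptome in 3 libraries and stood out in replicate 2. The summed level of the 16 listed genes was 9.38, 170, 7.20 and 6.85 CPM in replicates 1 to 4. CRA1 (AT5G44120, chromosome 5, 17756238 to 17758336, minus strand), which encodes a 12S cruciferin, had 159, 1394, 86 and 102 counts, 11.7-fold more CPM in replicate 2 than in the mean of the other libraries. The oil body gene OLEO2 (AT5G40420) had 10, 105, 12 and 11 counts, PER1 (AT1G48130) had 14, 94, 26 and 19 counts, and LEC1 (AT1G21970) had 1 count in replicate 4 alone. Named after their values were seen, the cruciferin gene CRU3 (AT4G28520) had 1, 998, 2 and 0 counts and the 2S albumin gene SESA1 (AT4G27140) 1, 403, 0 and 0 counts. Only 4 of the 16 members passed the filter, and their deviation in replicate 2 was 2.02 (adjusted Monte Carlo p 0.0016). The variation test gave an adjusted Monte Carlo p of 0.0014 with all libraries and 0.157 without replicate 2.

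**Figure D2:**
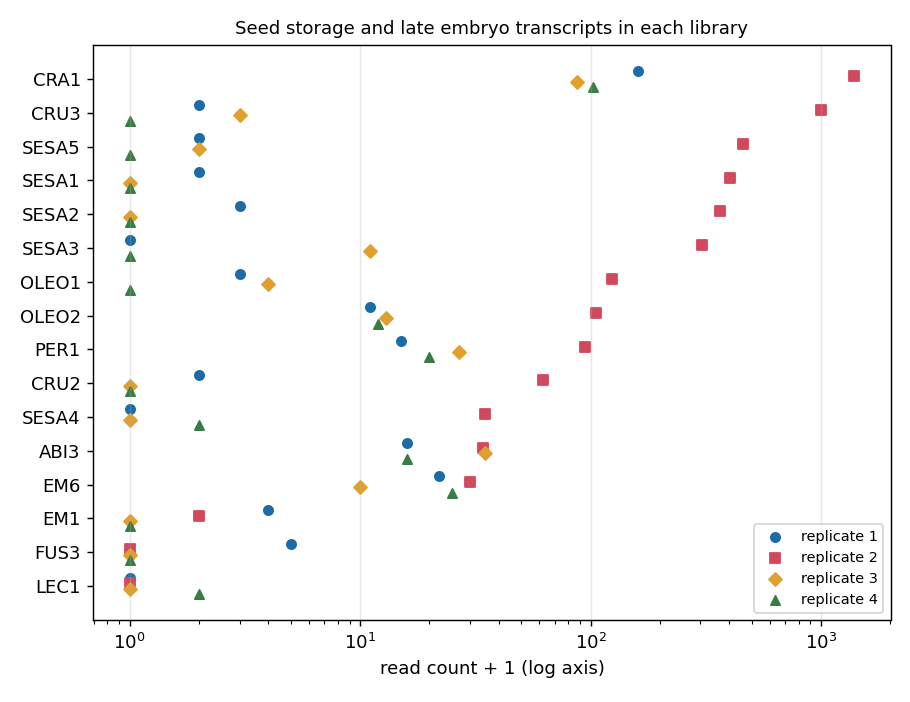
Read counts plus 1, on a log axis, of the 16 seed storage and late embryo genes in each library. Each symbol is a library, and CRA1 has 1394 counts in replicate 2 beside 159, 86 and 102 in the others.

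Root transcripts passed the variation test (adjusted Monte Carlo p 0.0014), and their excess beyond matched lists went from 0.0182 to between 0.0081 and 0.0102 in BCV when each replicate was left out. The deviations of the list were -0.07, 0.07, -0.14 and 0.11 in replicates 1 to 4, of which those in replicates 3 and 4 passed the test (adjusted Monte Carlo p 0.0045 and 0.0190), though not with the mean of the list in place of its median (both 0.0767). The iron transporter gene IRT1 (AT4G19690) had 4054, 3712, 2411 and 3683 counts, and the ferric reductase gene FRO2 (AT1G01580) 2403, 2092, 1379 and 2111 counts. The aquaporin gene TIP2;3 (AT5G47450) went the other way in replicate 3, with 174, 227, 319 and 204 counts. PYK10 was the highest member of the list, and the root stem cell regulator PLT2 (AT1G51190) was the lowest at 0.615 TPM.

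Touch and wounding transcripts were low in replicates 2 and 4 and high in replicate 3. Their median deviations were 0.10, -0.14, 0.15 and -0.10 in replicates 1 to 4, with adjusted Monte Carlo p of 0.0737, 0.0016, 0.0037 and 0.0187. Of the 18 members, 13 passed the filter. The calmodulin-like genes TCH3 (AT2G41100) and TCH2 (AT5G37770) were at 101 and 34.2 TPM, and TCH2 had 1260, 952, 1280 and 1010 counts. The xyloglucan-modifying gene TCH4 (AT5G57560) had 1370, 1213, 1557 and 1102 counts. CBF2 (AT4G25470) had 51, 21, 29 and 22 counts, and RRTF1 (AT4G34410) was lowest at 0.399 TPM. The variation test gave an adjusted Monte Carlo p of 0.0042, and 0.384 without replicate 3. With the mean of the list, the deviations in replicates 3 and 4 did not pass (adjusted Monte Carlo p 0.465 and 0.0767) and that in replicate 1 did (0.0098).

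Clock genes varied more than matched lists (adjusted Monte Carlo p 0.0014). The median deviation of the list passed in none of the 4 libraries, which does not test a shared shift, since morning and evening genes can go opposite ways. RVE8 (AT3G09600) had 1133, 857, 874 and 947 counts, RVE1 (AT5G17300) had 986, 1071, 1333 and 1003 counts, and PRR5 (AT5G24470) had 389, 507, 471 and 571 counts. GRP7 (AT2G21660) was the highest member at 1566 TPM and PRR9 (AT2G46790) the lowest at 1.47 TPM. The call was lost when any of 3 libraries was left out, with an adjusted Monte Carlo p of 0.215 without replicate 1, 0.0560 without replicate 2 and 0.643 without replicate 3.

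Flavonoid genes split into 2 directions in replicate 1. The late anthocyanin genes DFR (AT5G42800), with 200, 109, 83 and 106 counts, and LDOX (AT4G22880), with 188, 91, 74 and 85 counts, were highest there, as was PAP1 (AT1G56650), a MYB regulator of anthocyanin synthesis, with 40, 16, 11 and 21 counts. CHS (AT5G13930), the first enzyme of the pathway, had 9329, 11817, 11264 and 12186 counts and was lowest there, at 399 TPM on average. TT8 (AT4G09820), another regulator of the pathway, was highest in replicate 3, with 25, 16, 37 and 18 counts, and was the lowest member at 0.745 TPM. The list passed the variation test with an adjusted Monte Carlo p of 0.0022, and had 0.749 without replicate 1. Its median deviation in replicate 1 was -0.05 (adjusted Monte Carlo p 0.507), and with the mean of the list it was 0.24 and passed (adjusted Monte Carlo p 0.0022), so the list has no single direction there.

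The other 4 lists did not pass the variation test with all libraries, and none passed the test of deviation in any library. Without replicate 3 the abscisic acid and drought list passed the variation test (adjusted Monte Carlo p 0.0409). Ethylene genes lay at percentile 97.2, and their lowest member, ERF1 (AT3G23240), had between 0 and 6 counts per library (adjusted Monte Carlo p 0.851). Heat shock genes lay at percentile 19.5 with 4 of 10 members past the filter, from HSP70 (AT3G12580) at 24.6 TPM to ATHSP22.0 (AT4G10250) with 1 count in all (adjusted Monte Carlo p 0.831). Abscisic acid and drought genes lay at percentile 4.64, from COR47 (AT1G20440) at 172 TPM to RD29B (AT5G52300) at 1.47 TPM (adjusted Monte Carlo p 0.182). Cell division genes lay at percentile 45.1, from KNOLLE (AT1G08560) at 50.8 TPM to CYCB1;3 (AT3G11520) at 7.66 TPM (adjusted Monte Carlo p 0.891). Their percentile moved to 75.5 against all genes with a count, 59.35 with the mean of the list and 37.9 without length normalisation.

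**Figure D3:**
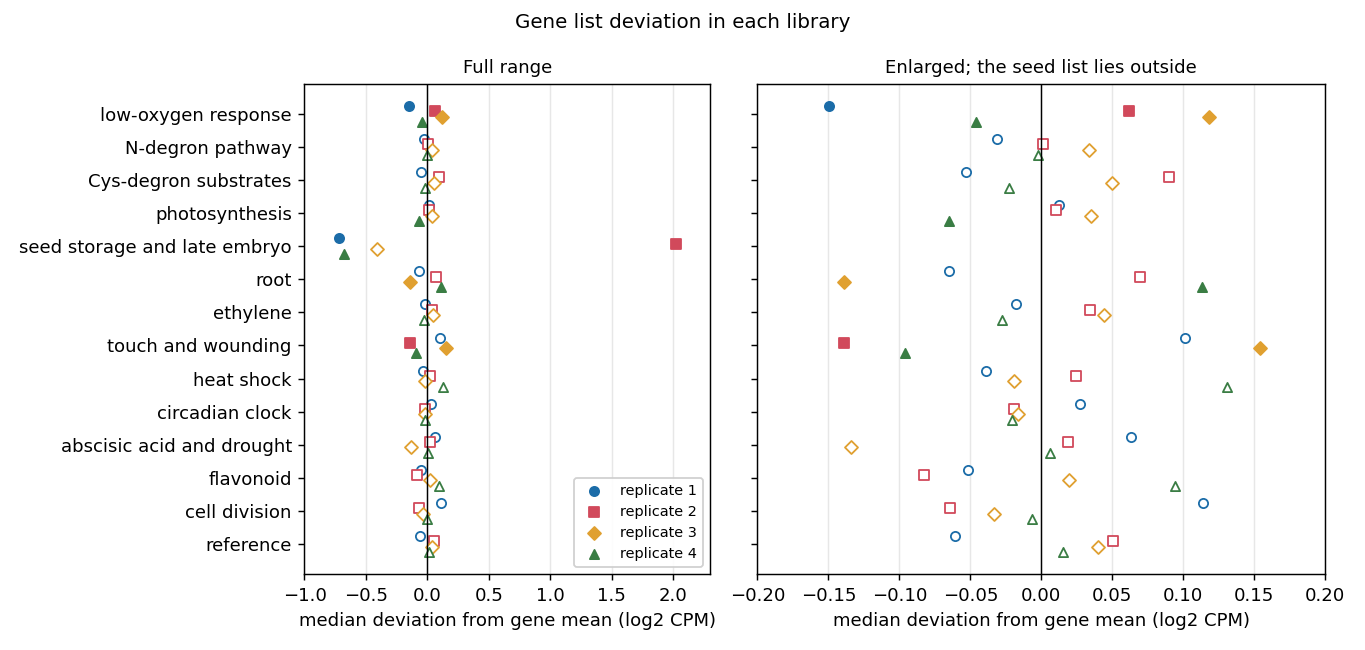
Median deviation of each gene list in each library from the gene means, in log2 CPM, over the full range (left) and enlarged (right). Filled symbols passed the Monte Carlo test after adjustment over the 56 pairs and open symbols did not. Low-oxygen transcripts lie at -0.15 in replicate 1 and 0.12 in replicate 3, and seed transcripts at 2.02 in replicate 2.

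Across the transcriptome the libraries were close to each other but not within counting error. Pearson correlations of log2(CPM + 1), across genes, ran from 0.993 to 0.995 over the 6 pairs, and genes are not independent replicates. The chi-square statistic per degree of freedom ran from 3.67 for replicates 2 and 4 to 7.60 for replicates 1 and 3, so no library repeated another within sampling noise. The median BCV was 0.0807 and the common BCV 0.0758. Counts of 8519 of the 19940 genes varied by more than counting error. With replicates 1 to 4 left out in turn, the number was 5276, 7027, 6173 and 7161, so it fell whichever library was removed. The first principal component, with 41.6% of the variance, separated replicate 1 from the others, and the second, with 33.4%, separated replicate 3.

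The most variable genes with a mean of at least 10 CPM followed several libraries. CRA1 led them, followed by AT5G36790, with 672, 91, 417 and 88 counts, which has the near-identical copy AT5G36700 and is uncertain. Lowest in replicate 1 were the lectin genes AT1G52060, with 116, 382, 290 and 418 counts, and AT1G52070, with 442, 977, 746 and 1001 counts, the dirigent-like gene AT4G11210, with 160, 389, 342 and 466 counts, and AT5G46900, with 190, 440, 390 and 468 counts. SEN1 (AT4G35770), a gene induced by darkness and sugar starvation, was also lowest there, with 689, 842, 1369 and 1198 counts. Lowest in replicate 3 were CYP82C4 (AT4G31940), with 2607, 2095, 1163 and 2346 counts, and the nicotianamine synthase gene NAS2 (AT5G56080), with 1129, 1130, 544 and 851 counts. The glycine-rich protein gene AT2G05510 was highest in replicate 2, with 426, 790, 363 and 335 counts.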

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

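The test of abscisic acid genes, the test of root share, the test of matched expression and the list of further seed transcripts were chosen after the results they bear on had been seen; the other tests were set before theirs. RAB18 and SAE1B were named after their values were seen. Of 131 results, 7 had a library that lay far from the other 3 relative to the whole range, where chance gives about 1 in 20, or 6.55. The design gives a single group, so no explanation by a difference between groups was tested.

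Seed transcripts were flagged through the median log2 TPM of the 4 members past the filter (gap over range 0.834, replicate 2) and OLEO2 (0.932, replicate 2). Seed tissue in the replicate 2 harvest, such as seeds that did not germinate, is a candidate explanation: among 24 further seed transcripts, 22 had at least 10 counts, their median log2 ratio of replicate 2 to the mean of the others was 1.89, and 17 of the 22 were highest in replicate 2, beside 22.6% of all 19940 genes. The 10 counts were summed over libraries, so a gene could enter through replicate 2 alone, and the genes left out had counts only there. The 22.6% covers genes that passed the expression filter, which these transcripts did not have to pass. The tables argue against an abscisic acid response of the seedlings, since the same ratio over the abscisic acid and drought list was 0.0218, with quartiles of -0.10 and 0.18, although RAB18 (AT5G66400) had 94, 321, 131 and 117 counts. The most abundant seed transcripts in replicate 2 were CRA1 at 53.8 CPM and CRU3, with 998 counts. Reads from a seed-bearing library in the same sequencing pool would look alike and stay open, as they were not tested.

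Low-oxygen transcripts were lowest in replicate 1 for 27 of 44 members, beside 28.5% of all genes. So were 7 of 12 reference genes and 1 of 13 touch and wounding genes. Replicate 1 also stood apart on the first principal component of all genes. A smaller share of root in that sample cannot be told apart, because the summaries of the root list disagree. By deviation root transcripts were lowest in replicate 3, where the low-oxygen list was at 0.118, but by median log2 TPM they were lowest in replicate 1, where 8 of 16 root genes were lowest against 6 in replicate 3. A shift of replicate 1 that depends on expression level would lower other genes of the same expression there. Random lists matched on expression had a median deviation of -0.0010 in replicate 1, beside -0.15 for the low-oxygen list. They are the random lists of the deviation test that the low-oxygen list had already passed, so this value is no separate evidence. Differences in air supply, age or harvest between the seedling samples were not tested and stay open.

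AT5G36790 and SAE1B (AT5G50580) were among the most variable genes and each has a near-identical copy. Reads that moved between the copies would leave an even sum, but the BCV of the summed counts exceeded the trend by up to 0.787. This BCV was computed directly from the counts and not by edgeR as elsewhere, so it cannot be set beside the other BCVs. For AT5G36790 it was 0.899 alone and 0.884 summed with its copy, where edgeR gave 0.461 alone. AT5G36700 had 10, 9, 9 and 3 counts and AT5G50680 had 0 in each library, so reads that map to both copies and were left out of the counts may still matter. Of the 100 genes with the highest excess BCV, 3% have a near-identical copy, beside 0% in the median matched list (Monte Carlo p 0.0354), so shared reads could account for few of them.

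HRE2 was low in replicate 4, with 62, 66, 66 and 44 counts (gap over range 0.891), and its counts did not vary beyond counting error (adjusted chi-square p 0.232). RVE1 was high in replicate 3 (0.838). The median log2 TPM of photosynthesis genes was 11.7 in replicate 1 and 11.6 in the others (0.8294). LEC1 (0.967) and ATHSP22.0 (0.982) each had 1 count in a single library, which shows no difference.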

How the results depend on the processing

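The alternative that let all genes with a count enter the variation test of lists was chosen after seeing the data; the others were planned. No paired analysis was possible because the labels give a single group. The alternative without organelle-encoded genes gave no value, since 0 such identifiers are in the table. The levels of PRT6, the number of genes with a count, the count of lists past the variation test (4 to 6) and the number of list and library pairs past theirs stayed within their limits under the alternatives run for each. The median BCV was 0.101 with no filter, 0.0689 with a mean CPM of at least 5, 0.0900 by DESeq2, and 0.0708 to 0.0857 when each replicate was left out; genes beyond counting error numbered 5276 to 7161 then. By construction the filters change which genes enter; for the other values here the cause was not tested unless stated. Without length normalisation the level percentile was 91.2 for low-oxygen and 77.9 for N-degron genes. Against all genes with a count it was 88.7 for N-degron genes and 78.4 for their substrates, and with the mean of the list 77.5 and 89.2. When each replicate was left out, the variation of a list beyond matched lists, in BCV, ran from 0.0028 to 0.0117 for low-oxygen, 0.0081 to 0.0102 for root, 0.0189 to 0.298 for seed, 0.0033 to 0.0171 for touch, 0.0014 to 0.0067 for clock and 0.0012 to 0.0256 for flavonoid genes; abscisic acid and drought genes passed at 0.0113 without replicate 3. With the mean of the list, low-oxygen genes in replicate 4 were at -0.0400 (adjusted Monte Carlo p 0.179), and flavonoid genes in replicate 1 reversed to 0.24 and passed (adjusted Monte Carlo p 0.0022). Dropping length normalisation, which shifts a ratio by the log2 ratio of the lengths, gave 1.46 for HRE1 to HRE2, 3.23 for PCO1 to PCO4, 1.3999 for PCO2 to PCO5, 0.66 for SUS1 to SUS4, -5.50 for HRE2 to RAP2.12, 2.102 for PRT6 to PRT1, 0.84 for ADH1 to PDC1, -1.88 for MAP2A to MAP2B and -1.04 for ETR2 to ETR1; RAP2.12 to RAP2.3 reversed to 0.28. The lowest Pearson correlation of a pair was 0.991 with a pseudocount of 0.25 and 0.997 over all genes. Depth limits genes such as NIP2;1, FHL, ZPR2 and most seed genes, whose counts are low enough that single reads move their levels.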

Other observations

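The lists of phosphate starvation and iron deficiency genes below were chosen after the data had been seen; their tests were set before their results. LCR67, BGLU19, UF3GT, F3H, PS2, PEPC1 and the further genes of those 2 lists were named after their values were seen. CRA1 was not in step with other seed storage genes. In replicate 2 it had 1394 counts beside 998 for CRU3, while in replicates 1, 3 and 4 it had 159, 86 and 102 counts beside 1, 2 and 0. Of the 16 seed genes, 7 had at least 30 counts in replicate 2 and under 5 in each of the other libraries. The plant defensin gene LCR67 (AT1G75830) had 18, 360, 30 and 22 counts, and the beta-glucosidase gene BGLU19 (AT3G21370) had 76, 548, 146 and 108 counts. The anthocyanin glycosyltransferase gene UF3GT (AT5G54060) went with DFR and LDOX, at 51, 28, 23 and 22 counts, while F3H (AT3G51240) went with CHS, at 1531, 1938, 1736 and 2105 counts.

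PS2 (AT1G73010), with 51, 161, 66 and 49 counts, and PEPC1 (AT1G17710), with 17, 73, 49 and 28 counts, 2 genes of the phosphate starvation response, were highest in replicate 2. A stronger phosphate starvation response in that sample may lie behind this: 11 other transcripts of the response had a median deviation of 0.187 in replicate 2 (Monte Carlo p 0.0002, the smallest possible), beside -0.16, 0.08 and -0.05 in replicates 1, 3 and 4. These transcripts were also at percentile 0.05 of matched lists in replicate 1 and 97.4 in replicate 3, so their variation was not confined to replicate 2. As an example, SRG3 (AT3G02040) had 749, 1141, 1090 and 1000 counts.

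CYP82C4, NAS2, IRT1 and FRO2, which act in iron uptake and handling, were each lowest in replicate 3. A weaker iron deficiency response over the whole list is argued against there. The 14 other iron deficiency transcripts had a median deviation of 0.0266 in replicate 3, at percentile 74.0 of matched lists. Their deviations were 0.01, 0.22 and -0.14 in replicates 1, 2 and 4, so in replicate 2 they were also high, at percentile 100, and the height of the phosphate genes there is not particular to them. AT3G12900 did go with the 4 genes, at 271, 314, 158 and 264 counts, while bHLH39 (AT3G56980) had 298, 495, 442 and 332 counts. A median over the list therefore cannot exclude a weaker response of some of its genes in replicate 3.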
